A study of Mus musculus with 16 samples.

How the data were processed

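Vagal ganglia carry the cell bodies of sensory neurons that run in the vagus nerve. They consist of the nodose part, whose neurons innervate the viscera, and the jugular part, whose neurons resemble those of dorsal root ganglia. Per the labels' protocols, ganglia of 15 mice of either sex were dissected at postnatal day 4. The mice carried a Cre driver of the vesicular glutamate transporter gene Slc17a6 and a Cre-dependent nuclear GFP. The tissue was dissociated with collagenase and trypsin, GFP-positive and DAPI-negative cells were sorted singly into 16 plates of 96 wells, and libraries were made with CEL-Seq2. CEL-Seq2 is a plate method that tags the 3' end of each polyadenylated RNA with a cell barcode and a unique molecular identifier (UMI) before linear amplification.

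The deposited file holds UMI counts, whole numbers per gene and cell that are not normalized, with 27066 genes and 1392 cells, and no gene has a total of 0. Reads were aligned with STAR to mm10 by the authors, per the submitters' processing notes; the versions, the gene annotation, the counting tool and the authors' filters on cells are not given in the sources used here. All columns could be assigned to a plate by name, no 2 cells held identical counts, and the names also show 2 runs of 8 plates each. The first run holds plates 2, 3, 6, 7, 8, 9, C and E, and the second plates 4, 5, 10, 11, 12, 13, 14 and 3B. All plates belong to 1 group, so the comparisons are between kinds of cells within plates and the replicate is the plate. Both classes of a comparison come from the same plate, which pairs them by design, and plate was a block in each model. Because the ganglia were pooled, plates can share animals, and p-values measure the spread between plates, which may be technical.

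Cells were kept with at least 1000 detected genes and at most 25% mitochondrial UMIs, which removed 0 cells. Counts were scaled to 10000 per cell and logged, the 2000 most variable genes were taken (scanpy 1.11.5), and 30 principal components were computed on values scaled per gene and capped at 10. A graph of shared neighbours (20 neighbours, at least 3 shared) was clustered with the Leiden method at resolution 1 (igraph 0.11.9). The genes of the 15 functional lists, mitochondrial, ribosomal and sex-linked genes took no part in clustering. A cluster was named nodose-like or jugular-like from the class with more of its fixed markers, and at least 3. A marker counted when at least 10% of the cluster's cells held a UMI and its level reached 0.25 of the mean over clusters. A nodose-like cluster was named Prox2/Runx3-like when at least 3 markers of that type were at least 2-fold above the mean of the other nodose-like clusters. A cluster led by cell cycle genes was left unnamed. Comparisons, gene lists, markers, tests and the rule for named genes were fixed before the data were examined. The 10% limit was set after seeing the data; a limit of 25% leaves 1 jugular-like cluster of 60 cells, led by Trpm8 and Foxp2, unnamed and was run as an alternative. Single genes among the top 10 of some clusters mark other cell types, among them Slc6a2 in cluster 6, Dcn in cluster 10, Kdr in cluster 15 and Gata3 in cluster 16.

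UMI counts were summed per plate and class and tested with edgeR 4.0.16 in R 4.3.3. The quasi-likelihood test (glmQLFit and glmQLFTest, robust) used TMM factors, filterByExpr, plate as a block and a two-sided test, over plates with at least 5 cells of each class. The limit was 2 cells for single clusters against the rest of their class and for each class and sex in the model of both. Benjamini-Hochberg adjusted p under 0.05 counted as passing. Genes used for clustering and cell type markers were left out of tests between classes. Levels of tested genes are CPM (UMIs scaled to a common library size) with TMM factors, as mean ± SD over plates. Marker levels and sums of marker lists, also those per cell or cluster, are CPM without TMM factors. Log2 differences carry an approximate standard error (SE), the absolute log2 difference divided by the square root of the quasi-likelihood F statistic. For the named genes, each list gave up to 2 passing genes with the largest positive and up to 2 with the largest negative log2 difference. Outside the lists, 5 genes each way were taken among those with at least 100 UMIs and the same direction in 75% of plates, and 16 genes of interest were always considered. The text gives part of the genes this rule names, and some are not reported here. Lists were tested with camera (limma 3.58.1, preset correlation 0.01), again with an estimated correlation, and with fry, and adjusted over the 15 lists. Of 500 genes in the lists, 492 were in the table. Cells with at least 1 Xist UMI and no UMI of Ddx3y, Uty, Kdm5d or Eif2s3y were called Xist-positive, and the reverse Y-positive. Shares carry exact binomial 95% intervals, which cover counting error only, and their spread over plates was tested by 100000 reassignments of cells to plates (permutation test of the chi-square statistic). Differences of medians per plate were tested by all sign flips (exact permutation test, two-sided). Gene positions are 1-based and come from an annotation of GRCm38, which is mm10, matched by symbol; it need not be the annotation the authors counted on. Genes on overlapping or opposite strands and pseudogenes can share reads, so their values are uncertain.

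The edgeR step was tested on simulated counts with 200 genes changed by known folds. For nodose-like against jugular-like sums with 12107 genes, it recovered 76.3% of genes changed 1.5-fold, 97.2% of those changed 2-fold and 100% of those changed 4-fold, and 4.3% of its calls were false. For Prox2/Runx3-like sums with 11646 genes the shares were 72.9%, 95.8% and 100%, with 5.3% false. For the sums by sex with 11724 genes they were 86.2%, 98.6% and 98.4%, with 3.7% false. Of 99 simulated lists with no change, camera gave an unadjusted p under 0.05 for 0 in the nodose-like and jugular-like sums and for 2 in the Prox2/Runx3-like sums, and fry for 9 and 13. In the data 5795 genes were called between nodose-like and jugular-like cells and 4088 for Prox2/Runx3-like cells. The simulation changed far fewer, so the shares above do not cover scaling when many genes change. Genes were simulated independently of each other and without plate effects, so these shares do not cover correlated genes either. In the data the estimated correlation within a list reached 0.237, for the Hox genes in nodose-like against jugular-like cells.

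Alternatives fixed beforehand were DESeq2 1.42.0, no filter on low counts, no replicate block, other limits on cells, other clustering resolutions (0.5 and 2), centring per plate, clusters and tests from separate parts of the UMIs, thinning to 3000 UMIs per cell, at least 10 cells per class, leaving out 506 possible doublets, classes by UMIs, 2 UMIs for the sex call, and leaving out each plate. Doublets were not otherwise removed, since single cells were sorted. Alternatives chosen after seeing the data were each run alone, cells with little glial RNA alone, the cycling cluster as nodose-like, testing clustering genes and markers too, leaving out the 2 plates without Xist-positive cells, the 25% limit, and the 3 clusters with most Prox2. The limit for glial RNA was 500 CPM summed over 7 markers; a limit of 1000 was set first and changed before a test was run with either, and 59 cells, or 4.24%, lie within 2-fold of it.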

Results

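The data are transcriptomes of single vagal ganglion neurons from mice at postnatal day 4, sorted by nuclear GFP in cells with a history of Slc17a6 expression. Slc17a6 encodes a vesicular glutamate transporter of sensory neurons. The 16 plates form 1 group and held 74 to 93 cells each, 1392 in all. Total UMIs per plate ranged from 5078592 in plate 11 to 8871398 in plate 5, and the plate medians from 51820 to 98802 UMIs and from 8371 to 10082 detected genes per cell. Single cells held 17714 to 223921 UMIs (median 70667) and 1.37% to 6.07% mitochondrial UMIs. Every one of the 1392 cells held UMIs of Slc17a6.

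The cells fell into 20 clusters, which need not be 20 kinds of neuron, since some clusters differed in glial RNA. Of these, 15 clusters with 1128 cells carried nodose-like markers, among them P2rx2, an ATP-gated channel. Jugular-like markers, such as Prdm12, a transcription factor of nociceptor development, and Prrxl1, named clusters 9, 10, 12 and 14 with 239 cells. Cluster 19, with 25 cells, was led by Top2a, Cenpf and Mki67, genes of dividing cells, and stayed unnamed. Clusters 7 and 8, with 144 cells, were Prox2/Runx3-like from Prox2, Grm5 and Slit2. Runx3 itself was low in them, led cluster 20 and stood at 39.0 CPM in cluster 6. Hs3st4, also a marker of the type, stood at 13.1 and 10.7 CPM in clusters 7 and 8 against 369.6 in cluster 4. Mgat4c stood at 21.2 and 16.2 CPM against 76.6 in cluster 18. Prox2 was highest in cluster 16, at 268.8 CPM against 210.0 and 182.1 in clusters 7 and 8. Cluster 16 had 2 markers of the type and so stayed among the other nodose-like cells. The other nodose-like cells therefore include cells with Prox2 or Runx3. As a background level, Prdm12 stood at 2.23 ± 1.49 CPM in nodose-like against 339 ± 50.4 in jugular-like cells (SD, n = 16 plates). A UMI of Prdm12 occurred in 8.69% of nodose-like cells (95% interval 7.11% to 10.49%), so shares of cells with a UMI are not read as expression here.

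**Figure D1:**
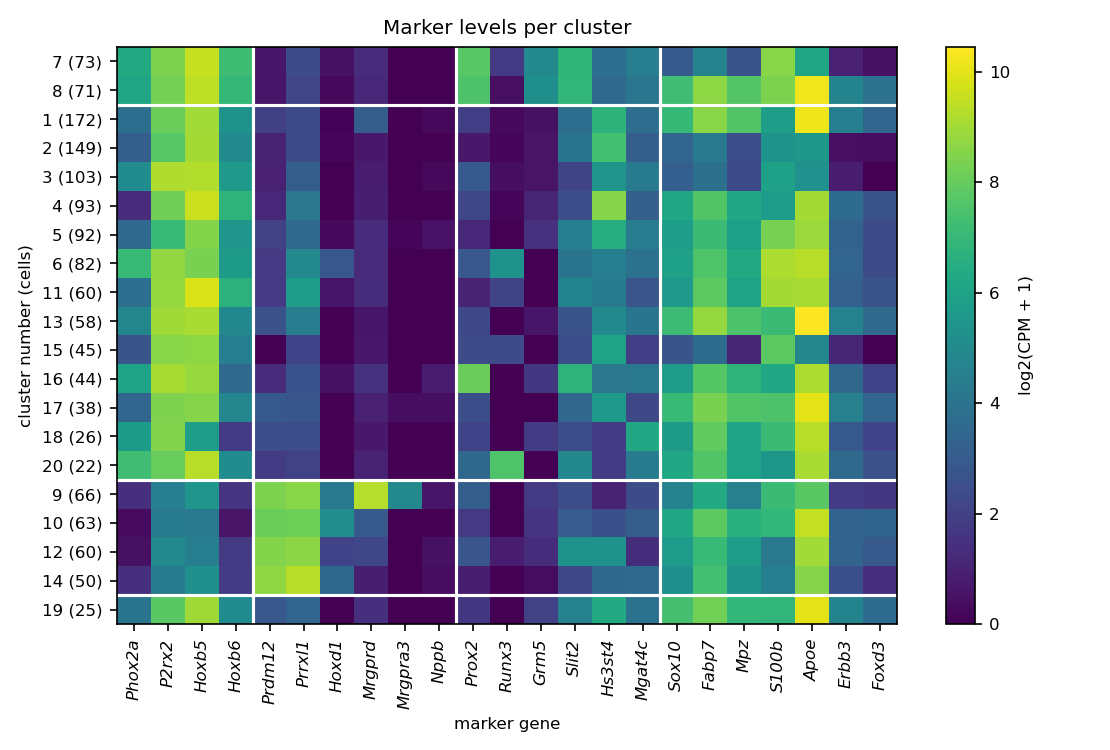
Level of cell type markers (horizontal axis; nodose-like, jugular-like, Prox2/Runx3-like and glial markers from left to right) in each of the 20 clusters (vertical axis, cells in brackets), as log2(CPM + 1) of summed UMIs by colour. White lines part the Prox2/Runx3-like clusters 7 and 8, the other nodose-like clusters, the jugular-like clusters and the unnamed cluster 19.

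The first question was whether plates held the same mix of neurons. Jugular-like cells made up 17.2% of all cells (239 of 1392, 95% interval 15.2% to 19.3%), with a plate mean of 17.1 ± 5.22% (SD, n = 16). Plates ranged from 9.88% in plate 12 to 27.96% in plate 3 and differed more than reassigned cells did (permutation test, p = 0.0433). In the plates of the first run the share was 19.2% (permutation p = 0.0436) and in those of the second 15.1% (permutation p = 0.533). The difference between plates was lost when values were centred per plate before clustering (permutation p = 0.499) and when cluster 12 was left unnamed (permutation p = 0.46). It was also lost without plates 2 and 3, an alternative chosen after seeing the data (15.9%, n = 14 plates, permutation p = 0.275). These plates held 22.6% and 27.96% jugular-like cells and no cell with Xist alone. Every other plate held 20 to 42 cells with Xist alone, which argues against the same mix of animals in plates 2 and 3. Their share of jugular-like cells therefore cannot be told apart from a difference between animals. Prox2/Runx3-like cells were 12.8% of nodose-like cells (144 of 1128, 95% interval 10.9% to 14.9%), with a plate mean of 12.8 ± 5.78% and a range from 3.17% in plate 7 to 26.8% in plate C (permutation p = 0.0155). Within runs the shares were 11.5% (permutation p = 0.00679) and 14.0% (permutation p = 0.244). The difference between plates remained without plates 2 and 3 (13.2%, permutation p = 0.0136), while at clustering resolution 2, where 88 cells carried the name, it was not found (permutation p = 0.136).

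**Figure D2:**
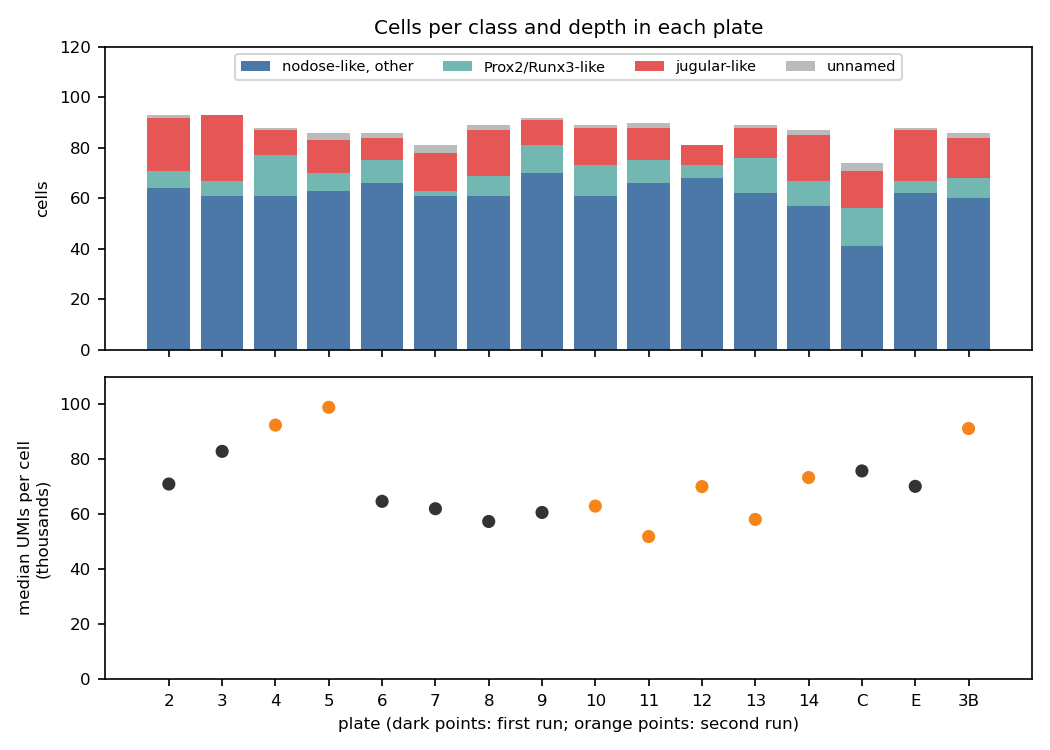
Upper panel: number of cells per plate in each class, stacked from 0. Lower panel: median UMIs per cell (axis in units of 1000), with plates of the first run dark and of the second run orange. Jugular-like cells range from 8 in plate 12 to 26 in plate 3, and Prox2/Runx3-like cells from 2 in plate 7 to 16 in plate 4.

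More UMIs and genes were detected in wells with nodose-like than in wells with jugular-like neurons. Plate medians were 72336 ± 14076 against 64927 ± 16093 UMIs per cell (higher in 13 of 16 plates, exact permutation p = 0.0341) and 9342 ± 558 against 8853 ± 632 detected genes (higher in 14 of 16 plates, exact permutation p = 0.00229). Within runs the UMI differences were 6454 (exact permutation p = 0.258) and 8363 (exact permutation p = 0.0781), and those of detected genes 528 (exact permutation p = 0.0312) and 449 (exact permutation p = 0.0703). In cells with less than 500 CPM of glial markers, a comparison chosen after seeing the data, plate medians were 70541 ± 14908 against 60029 ± 14366 UMIs (n = 16 plates, higher in 12, exact permutation p = 0.00363) and 9134 ± 524 against 8605 ± 595 detected genes (higher in 15 plates, exact permutation p = 0.00128). Prox2/Runx3-like and other nodose-like cells differed by 871 UMIs (SD 10816, n = 15 plates, exact permutation p = 0.783) and by -111 detected genes (SD 326, exact permutation p = 0.212), within the spread between plates.

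Glial RNA was found in many wells although neurons were sorted. The sum of 8 glial markers, led by Apoe and including Fabp7, was 1246 ± 224 CPM in nodose-like and 823 ± 327 CPM in jugular-like cells (higher in 13 of 16 plates, exact permutation p = 0.00177, Benjamini-Hochberg adjusted p = 0.00243 over 11 marker lists). The sum of 7 of these markers had a low and a high mode over cells, and 49.6 ± 8.28% of nodose-like against 25.9 ± 11.0% of jugular-like cells lay in the high mode above 500 CPM (16 of 16 plates, exact permutation p = 3.05e-05). In Prox2/Runx3-like cells the sum was 1597 ± 459 CPM against 1205 ± 221 in other nodose-like cells (13 of 15 plates, exact permutation p = 0.00287, adjusted p = 0.00526), and 55.8 ± 14.5% against 49.4 ± 9.15% of cells lay above 500 CPM of the 7 markers (exact permutation p = 0.17). Sums of the other marker lists in nodose-like against jugular-like cells were 251 ± 49.1 against 24.1 ± 24.2 CPM for sympathetic markers, 24.2 ± 4.00 against 1.83 ± 2.05 for endothelial markers and 224 ± 45.2 against 17.6 ± 15.6 for muscle markers. Mural markers went the other way, at 14.6 ± 3.31 against 112 ± 56.3 CPM. Each of these 4 lists had adjusted p = 4.8e-05 by exact permutation. Single markers were among the top 10 genes of neuron clusters, such as Slc6a2 in cluster 6, Kdr in cluster 15 and Gata3 in cluster 16. A sum can therefore come from neurons and need not be RNA of the cell type it is named for. Fibroblast markers (195 ± 49.6 against 207 ± 110 CPM, adjusted p = 0.789), immune markers (1.76 ± 1.91 against 2.03 ± 2.34, adjusted p = 0.789) and erythroid markers (6.96 ± 4.83 against 6.95 ± 7.89, adjusted p = 0.993) did not differ by more than the spread between plates in the exact permutation test. Between Prox2/Runx3-like and other nodose-like cells, endothelial markers were lower (4.55 ± 9.35 against 26.8 ± 4.03 CPM, adjusted p = 0.000269) and erythroid markers lower (1.51 ± 1.47 against 7.67 ± 5.46, adjusted p = 0.000168, exact permutation). The sympathetic (adjusted p = 0.502), fibroblast (0.549), mural (0.112), immune (0.245) and muscle lists (0.993) did not pass the same exact permutation test.

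**Figure D3:**
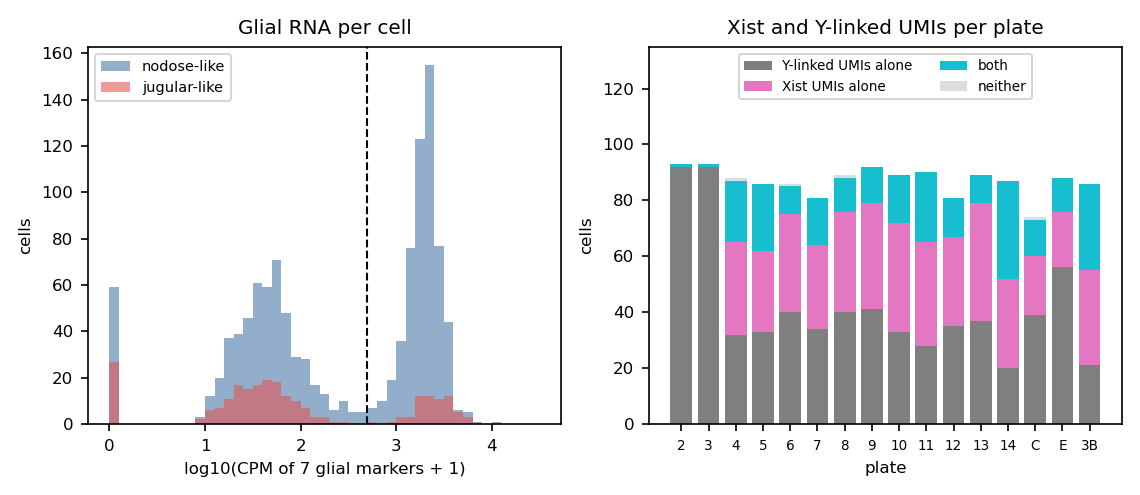
Left: number of cells by log10(CPM + 1) of 7 glial markers for nodose-like and jugular-like cells, with the limit of 500 CPM dashed. Right: cells per plate with Y-linked UMIs alone, Xist UMIs alone, both or neither, stacked from 0; plates 2 and 3 hold 0 cells with Xist alone and 92 cells each with Y-linked UMIs alone.

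The second question was how nodose-like neurons differ from jugular-like neurons. Jugular-like cells held more Tac1, Calca and Gfra3. Tac1, the precursor of substance P, stood at 1294 ± 362 CPM in jugular-like against 91.9 ± 31.7 CPM in nodose-like cells (SD, n = 16 plates). Calca, which encodes the peptide CGRP, stood at 993 ± 360 against 35.2 ± 23.8 CPM, and Gfra3, the artemin receptor, at 233 ± 53.3 against 4.83 ± 3.54 CPM. Nodose-like cells held more Ntrk2, the receptor of BDNF (690.2 ± 77.1 against 85.7 ± 39.9 CPM), more Cckar, a cholecystokinin receptor (160.3 ± 24.4 against 10.8 ± 6.11 CPM), and more Htr3a, a serotonin-gated channel (225 ± 44.2 against 21.4 ± 17.3 CPM). Each of these 6 genes differed in the same direction in 16 of 16 plates. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 5795 of 10579 genes passed, 2897 higher and 2898 lower in nodose-like cells. The balance depended on the filter and the method, with 3983 higher and 2636 lower without a filter on low counts and 3050 higher and 2617 lower in DESeq2. Within the first and the second run 4219 and 4020 genes passed. The count was 3855 over 13 plates without possible doublets, and 702 of 2726 genes with each cell thinned to 3000 UMIs.

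Among 12 tested mechanically activated and stretch channels, 2 were higher in nodose-like cells, 6 were lower and 4 were not called (2 and 6 adjusted over the list alone). The mechanosensitive channel Piezo2 (chromosome 18, 63010213 to 63387183) was 8.06-fold lower, at 69.0 ± 26.1 against 551 ± 172 CPM (log2 -3.01 ± 0.19 SE), and Tmem63a was lower by log2 -2.47 ± 0.21. The potassium channel Kcnk2, known as TREK-1, was higher by log2 0.69 ± 0.17. Of 16 TRP and ligand-gated chemosensory channels, 6 were higher, 6 lower and 4 not called (6 and 6 adjusted over the list alone). Htr3a (chromosome 9, 48899213 to 48911099; log2 3.57 ± 0.21) and Htr3b (2.52 ± 0.26) were higher, and Trpm3 (-1.26 ± 0.09) was lower. Trpv1, the capsaicin receptor, was lower by log2 -0.61 ± 0.19, at 206 ± 34.0 against 339 ± 159 CPM, and the ATP receptor P2rx3 was not called (58.2 ± 6.67 against 54.0 ± 11.0 CPM; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.227). Over the TRP list the median log2 difference was 0.08 while fry gave the opposite direction (adjusted p = 0.528).

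The gut hormone and metabolite receptors had 29 tested members, of which 15 were higher, 10 lower and 4 not called in nodose-like cells (17 and 10 adjusted over the list alone). The cholecystokinin receptors Cckar (chromosome 5, 53697776 to 53707705; log2 3.96 ± 0.13) and Cckbr (5.58 ± 0.28) were higher, as were Npy2r, a receptor of peptide YY (1.73 ± 0.21), and the oxytocin receptor Oxtr (11.4 ± 2.48 against 1.07 ± 1.43 CPM). Npy1r (-3.20 ± 0.33) and the lysophosphatidic acid receptor Lpar3 (-3.03 ± 0.20) were lower. The GLP-1 receptor gene Glp1r had 5 UMIs in 5 of the 1392 cells and was not tested. Of 18 neuropeptides, 7 were higher, 9 lower and 2 not called (7 and 9 adjusted over the list alone). Vip (log2 4.74 ± 0.14) and Pdyn, the dynorphin precursor (3.87 ± 0.26), were higher, and Calca (-4.86 ± 0.22), its paralog Calcb (-4.66 ± 0.17) and Tac1 (-3.83 ± 0.16) lower. Reads that Calca and Calcb share can be counted for either. Of 13 neurotrophic factor receptors, 4 were higher, 7 lower and 2 not called (4 and 7 adjusted over the list alone). Gfra3 was 50.2-fold lower (log2 -5.65 ± 0.20), while Gfra1, the GDNF receptor, was higher by log2 1.87 ± 0.23, and Ntrk3 was not called (38.8 ± 18.4 against 45.9 ± 22.1 CPM).

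Ion channels of excitability differed in most members. The 13 sodium channel genes divided into 5 higher and 8 lower in nodose-like cells (5 and 8 adjusted over the list alone). Scn3a was higher (139 ± 23.2 against 72.01 ± 25.1 CPM), and Scn10a and Scn11a, which encode the nociceptor channels Nav1.8 and Nav1.9, were lower by log2 -1.58 ± 0.13 and -1.76 ± 0.09. Of 45 potassium and HCN channel genes, 12 were higher, 27 lower and 6 not called (12 and 27 adjusted over the list alone). This was the only list that passed camera (Benjamini-Hochberg adjusted p = 0.00342, and adjusted p = 0.0144 with an estimated correlation). Kcnn2 (log2 -3.34 ± 0.15) and Kcnk12 (-4.80 ± 0.26) were lower, and Kcnq3, an M-current subunit, stood at 219 ± 22.0 against 14.0 ± 15.3 CPM. Of 16 calcium channel genes, 4 were higher, 10 lower and 2 not called (4 and 10 adjusted over the list alone), with Cacna2d1 (-1.32 ± 0.07) and Cacna2d2 (-1.45 ± 0.06) lower and Cacna1e (1.62 ± 0.15) higher. Glutamate, GABA and nicotinic receptors had 14 higher, 11 lower and 7 not called members (14 and 11 adjusted over the list alone). The nicotinic subunits Chrna3 (log2 4.02 ± 0.14) and Chrnb4 (4.10 ± 0.15), which are neighbours on chromosome 9, were higher, and the kainate receptor Grik1 was lower (-4.81 ± 0.12).

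Of 30 genes of transmitter release, 15 were higher, 11 lower and 4 not called (15 and 11 adjusted over the list alone). Ddc, which makes dopamine and serotonin from their precursors, was higher by log2 3.77 ± 0.26, and the release genes Syt7 (-3.08 ± 0.09) and Rims1 (-2.69 ± 0.11) were lower. Here the list's median was 0.16 while fry gave the opposite direction (adjusted p = 0.785). Slc17a6 itself was 581 ± 54.8 against 522 ± 55.8 CPM (log2 0.16 ± 0.04). Neurofilament and node of Ranvier genes had 5 higher, 9 lower and 3 not called members (5 and 9 adjusted over the list alone), with Ina (-1.93 ± 0.10) and Nefh (-0.33 ± 0.09) lower and Cntnap2 (1.15 ± 0.07) higher. Axon guidance and adhesion genes had 28 higher, 17 lower and 10 not called (29 and 18 adjusted over the list alone), with Cntn5 (4.66 ± 0.18) and Sema3d (4.61 ± 0.22) higher and the cadherins Cdh9 (-6.32 ± 0.23) and Cdh8 (-4.74 ± 0.26) lower.

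All 6 tested Hox genes were called, 4 higher and 2 lower in nodose-like cells (4 and 2 adjusted over the list alone). Hoxb2, Hoxb3, Hoxb4 (172 ± 23.9 against 6.88 ± 9.22 CPM) and Hoxc4 (19.4 ± 5.40 against 2.24 ± 2.73 CPM) were higher, and Hoxa2 (log2 -1.40 ± 0.23) and Hoxa3 (-1.44 ± 0.22) were lower. Sensory neuron transcription factors had 19 higher, 25 lower and 10 not called members (19 and 26 adjusted over the list alone). Eya1, a gene of cranial placodes, was 21.5-fold higher (log2 4.42 ± 0.21), and Prdm8 (-5.87 ± 0.11) and Pou4f2 (-7.02 ± 0.29) were lower. Of 25 immediate early and dissociation stress genes, 3 were higher, 6 lower and 16 not called (3 and 6 adjusted over the list alone), with Jun lower at 239 ± 33.7 against 527 ± 130 CPM and Nr4a1 higher (0.75 ± 0.23). The list's median was -0.06, and 0.08 with DESeq2. Outside the lists, Trim16 (4.58 ± 0.25) and Pter (4.22 ± 0.29) were among the genes with the largest positive and Rgs14 (-3.60 ± 0.32) and Fgf5 (-3.59 ± 0.31) among those with the largest negative differences. Besides the potassium and HCN channels no list passed camera, the smallest adjusted p of the others being 0.0838, while fry, which asks only whether a list moves one way and does not compare it with other genes, passed 10 of 15 lists. In cells with less than 500 CPM of glial markers, 4715 genes passed edgeR's test, of which 4542 were among the 5795.

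**Figure D4:**
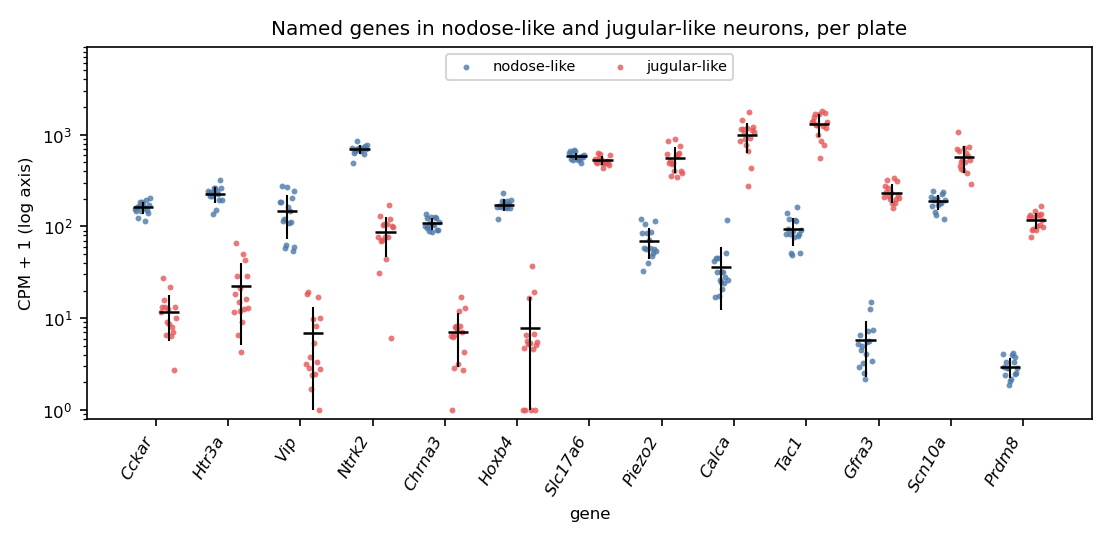
CPM + 1 on a log axis for 13 genes (horizontal axis) in nodose-like (blue) and jugular-like (red) cells; each point is 1 of 16 plates, the horizontal bar the mean and the vertical bar ± SD, ended at 1 where it would go lower. Prdm8 is at 1.98 ± 0.732 CPM in nodose-like and 116 ± 24.4 CPM in jugular-like cells, whereas the plates of both classes overlap for Slc17a6.

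The third question was how Prox2/Runx3-like neurons differ from other nodose-like neurons. Prox2/Runx3-like cells held much Piezo2, at 329 ± 40.5 against 33.5 ± 22.4 CPM (SD, n = 15 plates, higher in 15 of 15), and little Trpv1, Scn10a and Trpa1. Trpv1 stood at 19.3 ± 12.5 against 233 ± 34.0 CPM, Scn10a at 12.8 ± 10.7 against 215 ± 40.8 CPM and the irritant channel Trpa1 at 6.16 ± 4.90 against 135 ± 52.0 CPM, each lower in 15 of 15 plates. Neurofilament and node genes rose, such as Nefh (558 ± 91.9 against 268 ± 37.6 CPM) and the axonal adhesion gene Cntn1 (344 ± 43.5 against 114 ± 21.4 CPM). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4088 of 10260 genes passed, 2105 higher and 1983 lower in Prox2/Runx3-like cells. Which direction had more genes depended on the filter and the method, with 1625 higher and 2847 lower without a filter on low counts and 1875 higher and 1980 lower in DESeq2. Plate 7, with 2 such cells, did not enter. Within runs 2155 and 3147 genes passed, over 7 and 8 plates. The count was 2684 over the 6 plates with at least 10 cells of each class, 268 of 1862 genes after thinning, and 1671 over 6 plates in cells with less than 500 CPM of glial markers.

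Neurofilament and node of Ranvier genes were the list with the smallest camera p. Of 17 tested, 12 rose, 2 fell and 3 were not called (13 and 2 adjusted over the list alone; camera adjusted p = 1.08e-05, and adjusted p = 0.031 with an estimated correlation). Cntn1 (chromosome 15, 92051165 to 92341967; log2 1.61 ± 0.07), Nefh (1.06 ± 0.08) and Lgi2 (2.48 ± 0.16) rose, and Prph, a neurofilament protein of fine axons, fell by log2 0.26, from 1907 ± 170.4 to 1590.0 ± 116 CPM. Potassium and HCN channels had 21 higher, 11 lower and 10 not called members (21 and 12 adjusted over the list alone; camera adjusted p = 0.046, and adjusted p = 0.244 with an estimated correlation). The Kv4 partners Kcnip1 (3.95 ± 0.36) and Kcnip3 (2.25 ± 0.15) rose, while the Kv4 partner Kcnip2 (-3.27 ± 0.25) and Kcnq3 (-3.79 ± 0.26) fell. Of 12 sodium channel genes, 7 rose, 3 fell and 2 were not called (7 and 4 adjusted over the list alone; camera adjusted p = 0.0919, with a median of 0.43 and a mean of -0.17). Scn1a (1.15 ± 0.20) and Scn3a (1.07 ± 0.05) were higher and Scn10a (-4.01 ± 0.15) and Scn11a (-3.28 ± 0.18) lower. Of 17 calcium channel genes, 7 rose, 9 fell and 1 was not called (7 and 9 adjusted over the list alone; camera adjusted p = 0.883, with a median of -0.16 and a mean of 0.16). The T-type channel Cacna1g (2.56 ± 0.18) was higher and the N-type channel Cacna1b (-0.71 ± 0.04) lower.

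Receptors for gut hormones and metabolites fell: of 27 tested, 16 were lower, 5 higher and 6 not called (17 and 5 adjusted over the list alone; camera adjusted p = 0.00274, and adjusted p = 0.0414 with an estimated correlation). Npy2r (chromosome 3, 82538383 to 82548084; log2 -4.01 ± 0.41) and the prostaglandin receptor Ptger4 (-2.81 ± 0.24) fell, while P2ry12 (2.96 ± 0.20), Mc4r, the melanocortin receptor (2.21 ± 0.23), and Oxtr (0.86 ± 0.21) rose. Of 16 neuropeptides, 9 fell, 3 rose and 4 were not called (10 and 3 adjusted over the list alone; camera adjusted p = 0.0414, and adjusted p = 0.133 with an estimated correlation). Sst (-4.83 ± 0.22), Vip (-3.41 ± 0.34) and Tac1 (-2.46 ± 0.35) fell, and Penk, the enkephalin precursor, rose from 3.73 ± 3.02 to 79.5 ± 70.1 CPM (4.34 ± 0.36). Of 12 neurotrophic factor receptors, 7 fell, 2 rose and 3 were not called (8 and 2 adjusted over the list alone; camera adjusted p = 0.0178, and adjusted p = 0.0414 with an estimated correlation). Gfra1 (-4.09 ± 0.30) fell, and Gfra2, the neurturin receptor, rose from 26.5 ± 8.61 to 106 ± 19.1 CPM. Glutamate, GABA and nicotinic receptors had 14 lower, 7 higher and 8 not called members (15 and 7 adjusted over the list alone; camera adjusted p = 0.0314, and adjusted p = 0.0964 with an estimated correlation). Gabrg3 (-3.43 ± 0.40) was lower and Chrna4 (2.73 ± 0.19) higher.

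TRP and ligand-gated chemosensory channels had 7 lower, 3 higher and 5 not called members (7 and 3 adjusted over the list alone; camera adjusted p = 0.0576). Trpa1 (log2 -4.54 ± 0.16), Htr3b (-4.74 ± 0.20) and Trpv1 (-3.55 ± 0.17) were lower and Trpc7 (0.96 ± 0.15) higher. Among 11 mechanically activated and stretch channels, 3 were higher, 4 lower and 4 not called (3 and 4 adjusted over the list alone; camera adjusted p = 0.981). Piezo2 was 11.2-fold higher (3.48 ± 0.28) and Asic1 higher (0.83 ± 0.09), while Kcnk4, known as TRAAK (3.19 ± 2.88 against 13.8 ± 3.09 CPM), and Tmem150c (-1.76 ± 0.12) were lower. The list's median was -0.08 and fry gave the opposite direction (adjusted p = 0.81). Of 30 genes of transmitter release, 13 were higher, 10 lower and 7 not called (14 and 10 adjusted over the list alone; camera adjusted p = 0.159), with Ddc 7.18-fold higher (log2 2.84 ± 0.14) and Syt7 lower (-2.02 ± 0.08). The median was 0.13 and the mean just below 0. Axon guidance and adhesion genes had 17 higher, 21 lower and 15 not called (18 and 23 adjusted over the list alone; camera adjusted p = 0.661), with Ntng1 (2.42 ± 0.11) higher and the netrin receptor Unc5c (-2.61 ± 0.18) lower. Of 5 Hox genes, 2 were higher and 3 not called (2 and 0 adjusted over the list alone; camera adjusted p = 0.324), Hoxc4 by log2 2.10 ± 0.13 and Hoxb3 by 0.26 ± 0.06. Sensory neuron transcription factors had 14 higher, 16 lower and 16 not called members (17 and 16 adjusted over the list alone; camera adjusted p = 0.883, with a median of 0.07 and a lower direction in the test), among them Esrrg (2.54 ± 0.13) and Bcl11a (-4.29 ± 0.20). Stress genes had 7 higher, 5 lower and 12 not called (7 and 5 adjusted over the list alone; camera adjusted p = 0.792, with a median of 0.05 and a lower direction in the test), with Gadd45b (0.81 ± 0.17) and Dusp1 (0.53 ± 0.13) higher and Sox11 (-1.25 ± 0.17) lower. Camera passed 6 of the 15 lists, but 3 with an estimated correlation, and fry passed 11. Outside the lists, Piwil4 rose (4.15 ± 0.29) and the pro-apoptotic gene Bik fell from 7.69 ± 1.67 to 0.0718 ± 0.278 CPM. The latter level is below a floor of 3 counts over the class (0.27 CPM), so the size of Bik's log2 difference (-5.86 ± 0.46) is uncertain. The unplaced gene RP23-309G12.4 had 0 UMIs among 11117375 in Prox2/Runx3-like cells, at least 24.6-fold lower than in other nodose-like cells with a floor of 3 counts over the class.

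**Figure D5:**
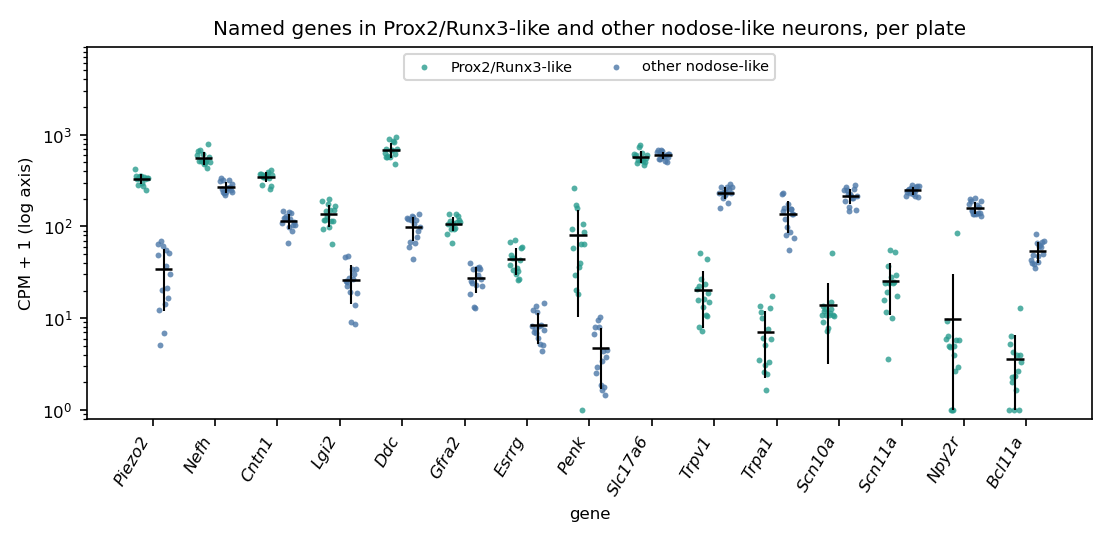
CPM + 1 on a log axis for 15 genes (horizontal axis) in Prox2/Runx3-like (green) and other nodose-like (blue) cells; each point is 1 of 15 plates, the horizontal bar the mean and the vertical bar ± SD, ended at 1 where it would go lower. Piezo2 is higher in Prox2/Runx3-like cells in 15 of 15 plates, and Scn11a is at 24.2 ± 14.3 against 245 ± 24.1 CPM.

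The fourth question was whether neurons of female and male mice differ, since mice of either sex were pooled. Xist, the RNA that coats the inactive X chromosome, and 4 Y-linked genes told cells apart: 458 cells were Xist-positive and 673 Y-positive, and 14 plates held both. All 5 X-linked genes that were called, of 386 tested, were higher in Xist-positive cells, by small amounts. Kdm6a, a histone demethylase, stood at 41.2 ± 5.16 against 28.7 ± 5.55 CPM, Kdm5c at 61.2 ± 9.26 against 48.9 ± 7.38 CPM and Ddx3x at 254 ± 11.6 against 212 ± 13.2 CPM (SD, n = 14 plates), each in 14 of 14 plates. The remaining X-linked genes were Pbdc1 and 5530601H04Rik; these 5 genes were picked after their values were seen. Gm29650, a long noncoding RNA gene on chromosome Y (1048393 to 1049134), stood at 22.1 ± 3.11 CPM in Y-positive and 0.0921 ± 0.151 CPM in Xist-positive cells.

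In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 36 of 11718 genes passed, 21 higher and 15 lower in Xist-positive cells, and 29 of them lie on autosomes. The largest positive differences were those of Tekt2 (chromosome 4, 126322121 to 126325688; 10.9 ± 3.40 against 2.65 ± 2.04 CPM, log2 2.09 ± 0.36), a gene of cilia, and of Cap1, an actin regulator (chromosome 4, 122859047 to 122886056; 50.04 ± 6.17 against 20.4 ± 9.34 CPM, log2 1.33 ± 0.15), each in 14 of 14 plates. Gpm6a (1.11 ± 0.23) and Pnpla3 (0.78 ± 0.10) were also higher. Cap1 overlaps Ppt1, which was lower in Xist-positive cells (-0.24 ± 0.03), so part of their reads can be shared. The antisense gene Tspan2os (-0.70 ± 0.10), the pseudogenes Rps13-ps1 (0.71 ± 0.11) and Rps13-ps2 (-0.69 ± 0.14) and the copy Tpm3-rs7 (-0.99 ± 0.19) are uncertain for the like reason. None of 13 genes chosen beforehand passed (Slc17a6, Piezo2, Trpv1, Oxtr, Npy2r, P2ry1, P2rx3, Calca, Tac1, Ntrk2, Ntrk3, Scn10a and Nefh). Tac1 stood at 333 ± 114 against 230.3 ± 84.0 CPM (adjusted p = 0.311) and Piezo2 at 173 ± 58.9 against 118 ± 55.8 CPM (adjusted p = 0.415) in edgeR's quasi-likelihood test. A model with a term for the difference of the sex effect between nodose-like and jugular-like cells called 0 of 8583 genes over 13 plates in edgeR's quasi-likelihood test (smallest adjusted p = 0.167), with 354 at an unadjusted p under 0.05. Its limit was 2 cells for each class and sex in a plate, and 5 of the 13 plates held at least 5 of each, so differences can have been missed. The count of 36 was 11 with no replicate block, 513 of 25842 genes with no filter on low counts, 51 in the first run and 8 in the second.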

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

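Prox2/Runx3-like neurons, a class rich in Piezo2, made up 26.8% of the nodose-like cells in plate C. The other plates of its run held at most 13.58%, and the gap made up 0.559 of the range of the run's 8 plates, above Dixon's 95% critical value. Chance alone puts about 1 in 20 groups past this value, and 12 groups of 8 plates were examined. The cause was not tested.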

How the results depend on the processing

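Limits of 500 or 2000 detected genes and of 10% mitochondrial UMIs kept the same 1392 cells. Values between classes under these limits were therefore unchanged in advance, and they are included in the counts of unchanged values below. The 25% limit likewise left the Prox2/Runx3-like comparison as it was. All 74 passing named genes between nodose-like and jugular-like cells kept their direction. Of 2738 values under alternatives, 2715 were unchanged in call, 19 weaker and 4 reversed. The reversed values belong to P2rx3 and Ntrk3, which never passed: -0.058 and 0.10 with values centred per plate, -0.051 and 0.050 with markers counted from 25% of cells. Between Prox2/Runx3-like and other nodose-like cells, 2638 of 2674 values were unchanged, 29 weaker and 2 stronger; 5 reversed, all of genes that passed and all with classes by UMIs: Kcnip2 1.19, Ntrk2 -0.092, Rims1 0.15, P2ry1 1.36 and Ntrk3 0.77. By sex, 419 of 458 were unchanged, 25 weaker, 7 stronger and 7 reversed, among genes that did not pass: Ntrk3 -0.020 with no replicate block; Slc17a6 -0.034 and Ntrk3 -0.58 in the first run; Calca -0.15 in the second; without 1 plate, Trpv1 ranged from -0.0036 to 0.11 and Calca from -0.050 to 0.32. Classes by UMIs took 325 nodose-like cells with any UMI of Prox2 or Runx3, against 144 cells by clusters. P2ry1 and Ntrk3 were high in cluster 20, which held Runx3 and which the cluster rule left among the other nodose-like cells. The cause was not tested for any reversal. Without 1 plate, counts of passing genes were 5475 to 5763, 3839 to 4045 and 24 to 54. With no replicate block they were 5187, 3503 and 11. Nodose-like against jugular-like counts were 702 after thinning to 3000 UMIs, where fewer genes were tested, and 3855 without possible doublets, over fewer cells. Prox2/Runx3-like counts were 2155 in the first run, 2684 with at least 10 cells, 268 after thinning and 1671 in cells with little glial RNA, each with fewer plates or genes; 3 lists passed camera with an estimated correlation against 6. By sex, counts were 513 with no filter on low counts and 8 in the second run. DESeq2 gave 5667, 3855 and 37, the last sharing 27 genes with the 36 of edgeR, with 0 opposite calls. Among Prox2/Runx3-like calls, 17 were opposite with classes by UMIs (2920 shared), 10 at resolution 2 (2684 shared) and 2 with the 3 clusters with most Prox2 (3655 shared); other alternatives gave 0. The jugular-like share no longer differed between plates with centring (p = 0.499), the 25% limit (0.46), the second run alone (0.533) or without the 2 plates with no Xist-positive cell (0.275), nor the Prox2/Runx3-like share at resolution 2 (0.136) or in the second run (0.244), by permutation test. Within runs, the UMI differences of 6454 and 8363 and that of 449 detected genes in the second run did not pass the exact permutation test, over 8 plates each.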

Other observations

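Within the nodose-like class, clusters differed in genes of peptides, receptors and channels. The genes given here were picked after their values were seen; each cluster was compared with the rest of its class by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, over plates with at least 2 cells of the cluster, so means and SDs of small clusters rest on few cells (median 2.5 per plate in cluster 18 and 2 in cluster 20). Cluster 18, with 26 cells, held Tac1 at 1621 ± 395.8 CPM against 53.2 ± 34.5 (SD, n = 8 plates, log2 5.20 ± 0.44 SE) and the GABA receptor subunit Gabrb2 at 94.3 ± 40.6 against 3.52 ± 1.33, but little Hoxb4, a gene of hindbrain position (13.5 ± 25.1 against 188 ± 16.2 CPM, adjusted p = 0.00193). Cluster 4 held the vasopressin gene Avp (179.3 ± 215.6 against 2.62 ± 4.96 CPM, n = 14 plates, log2 6.14 ± 0.50), Vip (769.4 ± 437.7 against 70.7 ± 39.3) and Cartpt (1101 ± 553.5 against 130.9 ± 27.1). Cluster 5 held somatostatin, Sst (248.6 ± 126.8 against 3.75 ± 2.33 CPM, n = 15 plates), and the pressure channel Piezo1 (23.1 ± 13.2 against 1.58 ± 1.63). The ATP receptor P2ry1 was high in cluster 6 (419.7 ± 110.3 against 40.1 ± 14.4 CPM, n = 14 plates) together with neurotensin, Nts (log2 6.09 ± 0.48), where Trpv1 was low (8.61 ± 5.56 against 233.1 ± 38.6). It was also high in cluster 20 (390.6 ± 105.7 against 46.9 ± 16.5, n = 7 plates), which held Runx3, Ntrk3 (497.2 ± 147 against 27.4 ± 5.38) and the acetylcholine transporter Slc18a3 (67.6 ± 27.5 against 1.61 ± 0.873).

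Among jugular-like cells, cluster 10 carried most Calca (2912 ± 772.6 against 341.2 ± 308.5 CPM, n = 15 plates, log2 3.59 ± 0.40) and the receptor Kit (243.4 ± 69.2 against 12.38 ± 7.48), and cluster 9, led by Mrgprd, held Scn10a (1008 ± 116.4 against 294.7 ± 113.7) and the potassium channel Kcnk18 (log2 4.34 ± 0.21). Cluster 14 held the transcription factor Pou4f2 (146.3 ± 45.2 against 8.69 ± 4.21 CPM, n = 13 plates) and Piezo2 (1038 ± 274.1 against 396.4 ± 130.7) with little Calca (log2 -6.38 ± 0.32). Cluster 12, led by the cold channel Trpm8, had little Piezo2 (8.58 ± 10.9 against 599.4 ± 116.4 CPM, n = 13 plates) and little Scn10a (16.8 ± 22.4 against 625.7 ± 130.4), by the same edgeR test.

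The tests below were chosen after the patterns were seen for free glial RNA, exchange between wells and Xist made by Y-positive cells, and the other predictions were written before their test. Glial RNA occurred in a part of the neurons, with 648 of 1392 cells above 500 CPM. Clusters 7 and 8 of the Prox2/Runx3-like class differed in it, with 8.22% and 100% of cells above. Clusters 3 and 13, both with Cckbr and Rtp1 among their top genes, had 1.94% and 100% above. Clusters 15 and 17, both with Kcng1 and Ceacam10, had 0% and 100%. Glial genes were not kept out of clustering, so such clusters can be parted by glial RNA rather than by kind of neuron. Free RNA spread evenly over a plate would leave the other 6 markers alike in cells with more and with less Apoe, but their mean was 874 ± 137 against 38.6 ± 41.0 CPM (SD, n = 16 plates) and at least 5.71 times higher in every plate, which argues against it. Glia sorted with a neuron would add UMIs; nodose-like cells above the limit held 4166 UMIs more (SD 9422, n = 16 plates, 12 higher, exact permutation p = 0.0978), which cannot tell. Glia of other animals that joined after dissociation would raise cells with both Xist and Y-linked UMIs, and these were 23.0% above and 19.4% below the limit, a difference of 3.58 points (n = 14 plates, exact permutation p = 0.144) where at least 10 were predicted. Of 135 cells with at least 5 UMIs of cell cycle genes such as Top2a, 85.9% lay above the limit; no biological explanation was tested.

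In 257 cells UMIs of Xist and of Y-linked genes stood together. Plates 2 and 3 held no cell with Xist alone, and there 1.075% of Y-positive cells had an Xist UMI (2 of 186, 95% interval 0.131% to 3.83%). The other plates had 17.65% to 63.64%, as exchange of RNA or barcodes between wells would give. Any other source that needs RNA of Xist-positive cells would give the same, so this share does not single out exchange between wells. Xist made by Y-positive cells or misaligned would also have appeared in plates 2 and 3, so the same 1.075% argues against it. For 2 neurons in a well both kinds would stand near their usual level, but the median of the lower relative level was 0.0588, and 8 of the 257 cells reached 0.25 in both, which leaves doublets as the source of few. No biological explanation was tested.

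The autosomal genes called by sex, such as Cap1, Tekt2 and Rpl3, could reflect variants of single animals among the 15 pooled mice. Genes on chromosome 4 correlated more within sex and plate than genes of different autosomes, by 0.048 (SD 0.0647, n = 14 plates, exact permutation p = 0.0156), but by 0.0221 without Cap1 (p = 0.278) and 0.0191 on chromosome 15 (p = 0.0753), the last 2 checks added after the first, so this cannot tell. If sex acted alike in every animal, Y-positive cells of plates 2 and 3 would lie in the range of the other plates' Y-positive cells as often for these genes as for others. Instead 6 of 29 genes lay outside in both plates, among them Cap1 and Rab6a, against 3.35% of other genes, a ratio of 6.19 (Fisher's exact test, two-sided p = 0.000357). The sums by sex mix both classes of neurons. Plates 2 and 3 held 22.6% and 27.96% jugular-like cells, against 17.1 ± 5.22% over all plates. The excess can come from the mix of cells as well as from the animals, so this test cannot decide. It does not exclude an effect of sex for any of these genes.

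Swapping labels within plates asked whether chance could give as many calls. Of 30 labellings by sex, only 1, the real one, reached 36 genes, the highest other count being 2. At that number of labellings, spread between plates alone did not give as many calls. Plates can share animals, so a chance difference between the pooled animals could repeat in every plate, and the swaps cannot exclude it. Between nodose-like and jugular-like cells (1 of 30, 5795 against 0) and for Prox2/Runx3-like cells (1 of 30, 4088 against 0) the swaps decide nothing. These classes come from clusters of the same cells, so swapped labels give few calls in any case. With clusters from 1 part of the UMIs and the test on the other, 4416 and 2952 genes passed, of which 4237 and 2781 were among the 5795 and 4088.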
